A study of Rattus norvegicus with 10 samples.

How the data were processed

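RNA was measured on 10 Affymetrix whole-genome rat expression arrays, 5 with axonal RNA from embryonic day 16 rat dorsal root ganglia and 5 with axonal RNA from adult ganglia. Per the labels' protocols, ganglion explants were kept for 4 days in chambers with compartments, axons longer than 1 cm were collected from the outer compartment, RNA was extracted with Trizol, and biotin-labelled cRNA was made with an in vitro transcription kit. The labels call the 5 samples of each stage biological replicates, and whether a sample pooled several animals is not given in the sources used here.

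The values deposited by the authors are on a log2 scale and were made with RMA (robust multi-array average), per the submitters' processing notes. The software version, the options and whether all 10 arrays were processed together are not given in the sources used here. The base of the logarithm was taken as 2 from the range of the values. Array medians lay between 2.85 and 3.14, no centring of genes was visible, and the table holds no detection calls. RMA shares information between arrays and compresses differences of weak probe sets, so folds of genes near the background understate the change. The number of arrays limits the precision.

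The table holds 31099 probe sets, of which 57 are controls. The platform annotation pairs 20826 probe sets with a single gene symbol and 436 with several, and 9780 are unnamed here. Gene numbers of 20758 single-symbol probe sets were found in a newer rat gene table, and 0 symbols needed an update. A gene was represented by its single-symbol probe set with the highest mean over all 10 arrays, which gave 14217 genes, 4525 of them with several probe sets. Actb had no probe set with a single symbol and was not analysed as a gene. No pseudocount or filter on weak values was used.

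Adult minus embryonic differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) over all 10 arrays, and every adjusted p of a gene is limma's p after Benjamini-Hochberg adjustment over the 31042 probe sets that are not controls. The threshold was an adjusted p of 0.05. In total 30 gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, two-sided, with adjustment over the 30 lists. The lists comprised groups of axonal, neuronal, immune and housekeeping genes and markers of the other cell types that a ganglion culture could hold. The level of background on an array was the 95th percentile of 98 probe sets of 86 genes restricted to other tissues. A gene was above background in a stage when it exceeded that level on all 5 arrays. For a named gene below it on all arrays of a stage, the fold is a lower bound, taken against the mean of the higher of the background level and the gene's own value on each array, and its measured means or log2 change are also given. Control probe sets and array summaries were compared by two-sided exact permutation tests over a family of 11 measures. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

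Genes named in the text followed a rule. It took the 8 largest rises and 8 largest falls among called genes with a log2 change of at least 1, no overlap between stages and no probe set called the other way. It added up to 3 called members of each list called by camera, up to 2 called members of each other list, and 8 genes of sensory axons whatever their values, of which 7 could be analysed (all but Actb). Other genes named in the text were chosen after their values were seen.

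The groups, the gene lists, the tests, the rule for named genes and the processing alternatives were fixed before the data were examined. The alternatives were quantile, cyclic loess and median scaling, a filter on weak probe sets, another variance model, array weights, the replicate number as a block, other summaries of a gene's probe sets, other set tests, other background levels and leaving out each array. Chosen after seeing the data were the split of the arrays by the spread of their values, the exact permutation test of each list's mean per array, and most tests of explanations in the closing section. After an exploratory fit had been seen, the matching of older symbols was corrected because it had placed a wrong gene on the macrophage and leucocyte list. An older symbol is now used only where it is unambiguous.

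The fit was tested on simulated data with 50 genes at each of 4 sizes of change. It recovered 0% of genes changed by 1 on the log2 scale, 28% at 2, 62% at 4 and 94% at 6, with 4 false calls among 96. In the simulated list test the shifted list was called and 0 other lists were, but the simulation had no shared structure between arrays such as the deposited values show.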

Results

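The series compared the transcripts of sensory axons from embryonic and adult rats. Dorsal root ganglia hold the cell bodies of sensory neurons, and the RNA came from axons that had grown out of ganglion explants into a separate compartment. There were 5 arrays from embryonic day 16 and 5 from adult animals. Above the background level were 5651 to 8682 genes on embryonic arrays and 5013 to 9791 on adult arrays. The standard deviation of all values on an array ranged from 1.49 to 2.07 on the log2 scale. In 4 arrays, embryonic replicates 1 and 5 and adult replicates 4 and 5, it was above the middle of this range, and these held 7954 to 9791 genes above background.

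The poly-A control transcripts, which are added to RNA before labelling, were at 10.66 ± 1.70 (SD, n = 5) on adult arrays and 2.26 ± 0.31 on embryonic arrays, with an exact permutation p of 0.0079, or 0.044 after adjustment over 11 measures. A 5S ribosomal RNA control probe set was at 8.69 ± 1.16 on embryonic and 4.66 ± 1.13 on adult arrays, with the same p. Both measures separated the stages completely, so labelling and stage cannot be told apart by any gene below. Hybridisation controls averaged 11.47 in both stages. They did follow the spread of the arrays, at 9.15 to 10.76 on the 4 arrays of wide spread and 11.63 to 12.83 on the other 6, here called narrow. Differences between 3' and 5' probe sets, a sign of RNA integrity, were large in both stages. On the log2 scale they averaged 4.94 on embryonic and 4.69 on adult arrays for actin, and 4.50 and 4.29 for Gapdh. Over single arrays they ranged from 3.03 to 6.04 for actin. Exact permutation p values between stages were 0.74 and 0.71, which does not show that the RNA was intact.

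**Figure D1:**
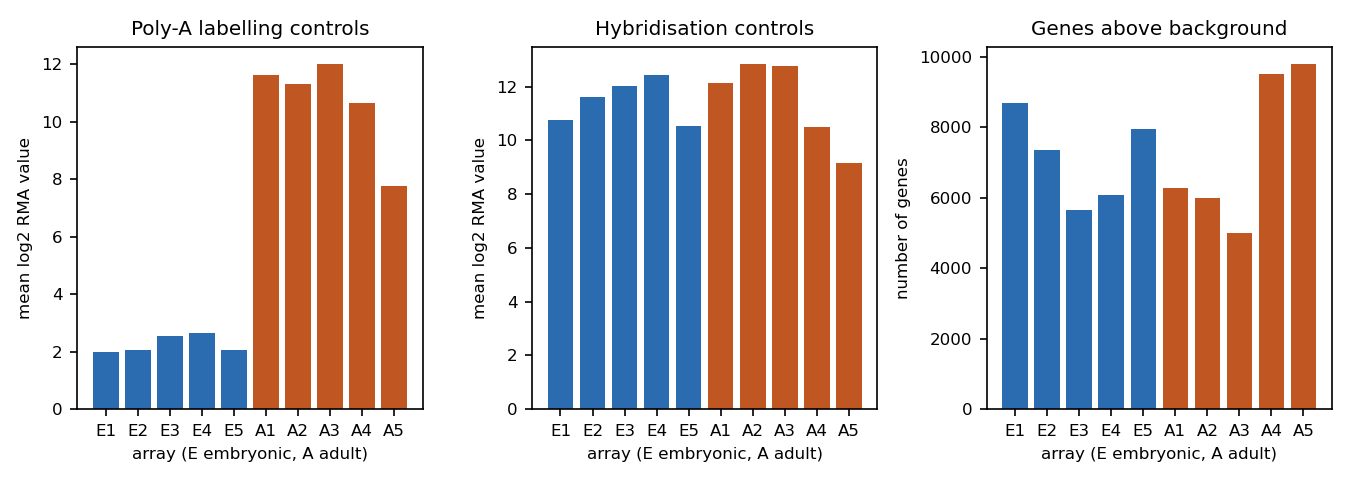
Mean log2 values of the poly-A labelling controls (left) and the hybridisation controls (middle), and number of genes above background (right), with 1 bar for each of the 5 embryonic (E, blue) and 5 adult (A, orange) arrays. Poly-A controls lay between 7.75 and 11.99 on adult arrays and between 2.00 and 2.65 on embryonic arrays.

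The question was which axonal transcripts differ between embryonic and adult neurons, with growth and pain as themes of the series. In adult samples 12 of 33 macrophage and leucocyte markers and 4 of 52 cytokine, chemokine and complement genes were higher, and 7 of 24 neurofilament, tubulin and microtubule genes and 7 of 39 motor genes were lower. Camera called these 4 lists, and 0 of 30 lists were called with an estimated correlation (lowest adjusted p = 0.068 with an estimated correlation). The chemokine Cxcl13, below background on all embryonic arrays, was at least 66.4-fold higher in adult samples (9.73 ± 0.67 against 2.39 ± 0.26, SD, n = 5; adjusted p = 8.1e-06). Apc2, a microtubule-binding relative of the Apc tumour suppressor, had a log2 change of -7.79 ± 0.63 (SE; 3.65 ± 1.51 against 11.45 ± 0.42, SD; adjusted p = 0.00057) and was above background on 2 of 5 adult arrays. Calca and Trpv1, genes of pain-sensing neurons, did not pass the test, and Trpv1 was above background on only 2 embryonic and 0 adult arrays. Other called genes named below that were below background on all arrays of a stage have only a lower bound of their fold. It was at least 16.2-fold for Tbc1d4, 21.3-fold for Cxcl2, 7.89-fold for RT1-Da, 6.79-fold for Psmb8 and 6.24-fold for Cd74, and at least 22.3-fold lower in adult samples for Unc13c, 16.4-fold for Dcx and 5.67-fold for Hbe1.

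In all, 179 of 14217 genes passed the threshold, 87 higher and 92 lower in adult samples, and the smallest of these changes was 1.35 on the log2 scale. These counts correspond to 258 probe sets, 116 higher and 142 lower. At an unadjusted p under 0.05 there were 1890 genes. The stages did not overlap for 503 genes, 3.54% of those tested, against 0.794% by chance. Of 66 called genes with several probe sets, 8 had another called the same way and 0 had one called the other way. The split between higher and lower genes was 109 to 61 without embryonic replicate 1, 81 to 151 without embryonic replicate 4 and 97 to 151 without adult replicate 5. Leaving out 1 array gave 117 genes (embryonic replicate 2), 106 (embryonic replicate 3), 107 (embryonic replicate 5), 117 (adult replicate 1) and 101 (adult replicate 4), and 150 to 339 probe sets over all 10 omissions. Of 35 called genes named here, 15 lost the call without at least 1 array, Dcx in 9 of 10 omissions and Kif5a, Rab3a, Chga and Cox6b1 in 8. Quantile scaling also ended the calls of Kif5a (adjusted p = 0.090), Nefl (0.057), Ccnd2 (0.078) and Rab3a (0.093). With the spread of the arrays as a block there were 276 genes. The 6 arrays of narrow spread gave 168 genes, 65 of them among the 179, and the 4 of wide spread gave 0 by limma, with 2810 at an unadjusted p under 0.05.

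Macrophage and leucocyte markers had the highest median change of the 30 lists over all 10 arrays, though not within the 4 of wide spread, where cell cycle genes (2.32) and cytokines (1.90) lay above its 1.87. Of its 33 genes, 12 rose and 0 fell, and 19 rose when adjusted over the list alone. Adgre1, the F4/80 antigen of macrophages, rose by 6.69 ± 0.75 on the log2 scale (SE, n = 5; adjusted p = 0.0022) and was above background on 1 of 5 embryonic arrays. Lyz2, the lysozyme of macrophages, reached 12.27 ± 0.45 (SD) in adult samples from 5.58 ± 1.84, a change of 6.69 ± 0.75 (SE; adjusted p = 0.0022). The Fc receptor Fcgr2b rose by 6.04 ± 0.67 (adjusted p = 0.0022) and the leucocyte actin-bundling protein Lcp1 by 5.41 ± 0.68 (adjusted p = 0.0052). The median change of the list was 2.74 (camera adjusted p = 2.5e-17; adjusted p = 0.068 with an estimated correlation). It was 1.87 within the 4 arrays of wide spread and 3.11 within the 6 of narrow spread. In embryonic samples 4 of the 33 genes were above background on all arrays, and in adult samples 19.

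Of 52 cytokines, chemokines and complement components, 4 rose, with 15 higher and 2 lower when adjusted over the list alone. Besides Cxcl13, the chemokines Cxcl2 (5.07 ± 0.72, adjusted p = 0.0092) and Ccl2 (4.69 ± 0.81, adjusted p = 0.025) rose on the log2 scale. Antigen presentation had 4 of 25 genes higher, and 7 when adjusted over the list alone, among them RT1-Da (3.98 ± 0.65, adjusted p = 0.019), a class II molecule, and its invariant chain Cd74 (3.06 ± 0.43, adjusted p = 0.0092). Psmb8, an immunoproteasome subunit and the only called gene among 32 of the interferon response and 36 of the proteasome, rose by 3.76 ± 0.65 (adjusted p = 0.024). The interferon response had 4 genes higher when adjusted over the list alone, and the proteasome 1. Camera called cytokines, antigen presentation and the interferon response higher (adjusted p = 9.9e-10, 3.1e-07 and 6.5e-05), and each had an adjusted p = 0.068 with an estimated correlation. The lysosome and endosome list had 1 of 35 genes higher, and 4 when adjusted over the list alone. That gene was the protease Ctsl (3.72 ± 0.60, adjusted p = 0.018). The list was called higher (adjusted p = 3.2e-05; adjusted p = 0.40 with an estimated correlation). Genes outside these lists with large rises were Akr1b8, an aldo-keto reductase (5.74 ± 0.97, adjusted p = 0.022), the C-type lectin Cd302 (5.26 ± 0.87, adjusted p = 0.020) and the Rab GTPase-activating protein Tbc1d4 (5.11 ± 0.53, adjusted p = 0.0015). The other probe set of Tbc1d4 changed by 1.63 (adjusted p = 0.31).

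**Figure D2:**
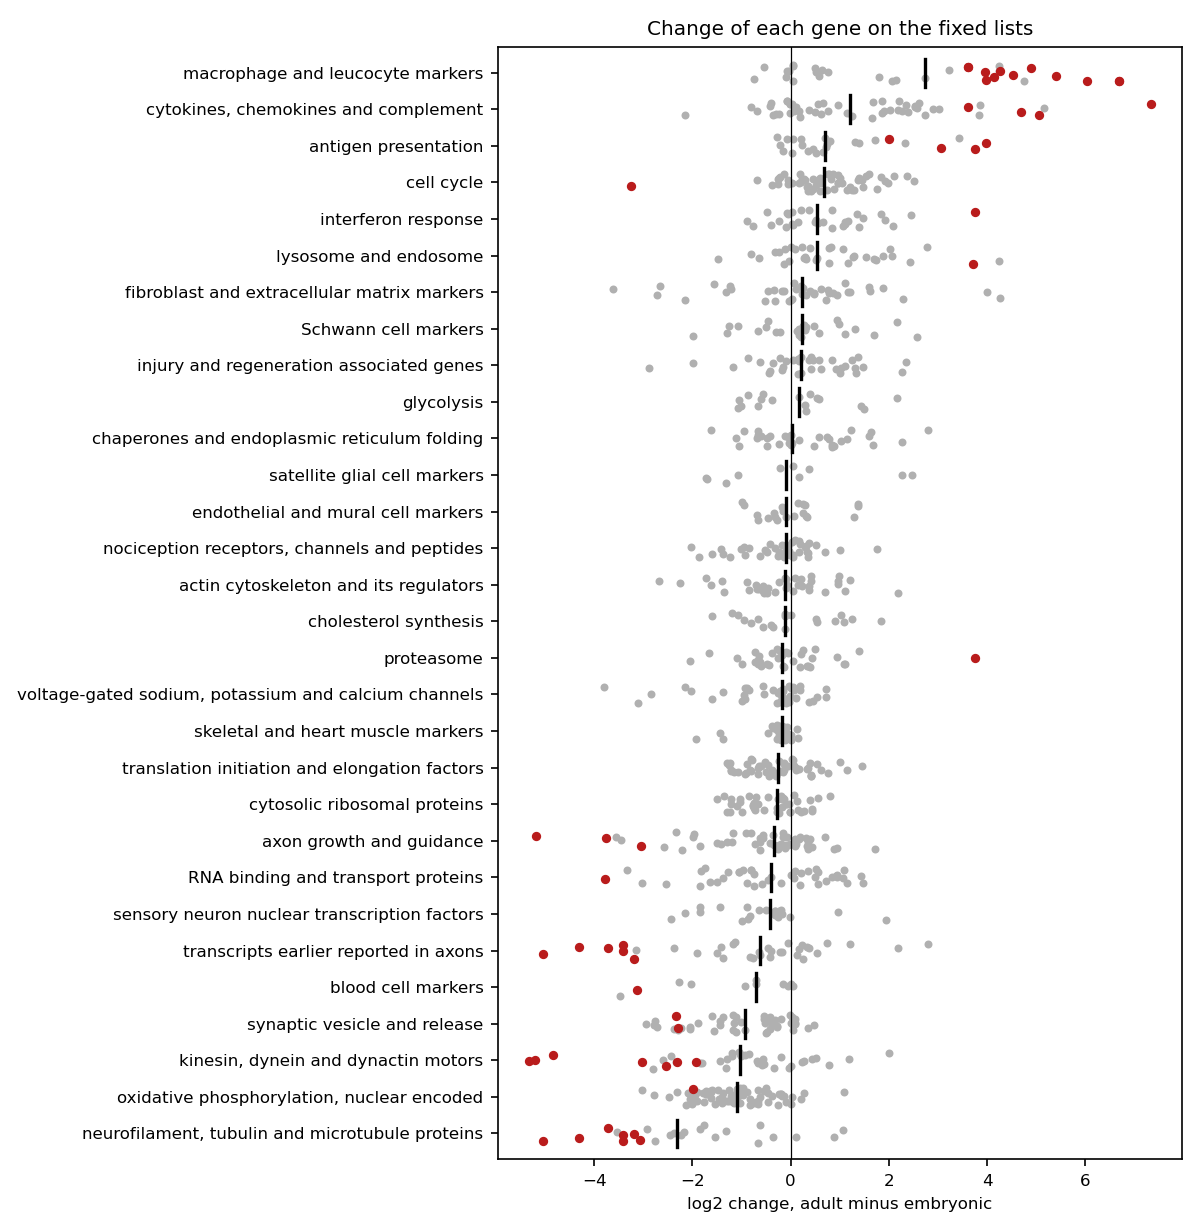
Log2 change, adult minus embryonic, of each gene on the 30 lists. Each point is a gene, red where its adjusted p was under 0.05 and grey otherwise, with vertical scatter for legibility, and black bars are list medians. Macrophage and leucocyte markers had a median of 2.74 and the neurofilament, tubulin and microtubule list a median of -2.31.

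Of 24 neurofilament, tubulin and microtubule genes, 7 fell and 0 rose, and 15 fell when adjusted over the list alone. Mapt, the microtubule-associated protein tau, changed by -5.05 ± 0.67 (SE, n = 5; adjusted p = 0.0069), and by -3.52 (adjusted p = 0.056) with probe sets of shared sequence left out. Peripherin, Prph, an intermediate filament of peripheral neurons, changed by -4.32 ± 0.71 (adjusted p = 0.020), from 11.49 ± 0.82 (SD) to 7.17 ± 1.59. The light neurofilament Nefl changed by -3.72 ± 0.69 (adjusted p = 0.036). Neuronal tubulin Tubb3 changed by -3.18 ± 0.51 (adjusted p = 0.016), and by -0.03 (adjusted p = 0.99) with the same omission. The list median was -2.31 (camera adjusted p = 3.8e-15; adjusted p = 0.086 with an estimated correlation), -2.38 within the arrays of wide spread and -2.58 within those of narrow spread.

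Of 39 kinesin, dynein and dynactin genes, the motors that carry cargo along microtubules, 7 fell, with 17 lower and 2 higher when adjusted over the list alone. The kinesin heavy chains Kif5c (-5.32 ± 0.50, adjusted p = 0.0010) and Kif5a (-5.20 ± 1.00, adjusted p = 0.044) and the vesicle motor Kif1a (-4.85 ± 0.45, adjusted p = 0.0010) had the largest falls. Other probe sets of Kif5c changed by -2.68 (adjusted p = 0.055) and -1.89 (adjusted p = 0.17). Those of Kif1a changed by -4.39 (adjusted p = 0.016) and -0.18 (adjusted p = 0.97), and those of Kif5a were also called lower. The list was called lower (adjusted p = 2.3e-09; adjusted p = 0.071 with an estimated correlation). Axon growth and guidance had 3 of 53 genes lower, and 6 when adjusted over the list alone. They were Dcx, doublecortin of migrating and growing neurons (-5.18 ± 0.96, adjusted p = 0.035), Crmp1 (-3.76 ± 0.51, adjusted p = 0.0074) and the growth cone protein Basp1 (-3.04 ± 0.33, adjusted p = 0.0022). The other probe set of Dcx had a log2 change of 0.03 (adjusted p = 0.99). The axon growth list was called lower (adjusted p = 9.5e-05; adjusted p = 0.13 with an estimated correlation). Gap43, another growth cone protein, was at 11.02 ± 0.86 (SD) in embryonic and 9.85 ± 1.00 in adult samples (adjusted p = 0.52). Synaptic vesicle and release genes had 2 of 47 lower, Rab3a (-2.34 ± 0.44, adjusted p = 0.041) and Chga (-2.30 ± 0.42, adjusted p = 0.034), and 6 when adjusted over the list alone. The other probe set of Rab3a changed by -0.31 (adjusted p = 0.88). The synaptic list was called lower (adjusted p = 4.3e-08; adjusted p = 0.070 with an estimated correlation). The large falls outside these lists included Nrep (-6.39 ± 0.86, adjusted p = 0.0072), the release factor Unc13c (-5.55 ± 0.53, adjusted p = 0.0010), Sytl3 (-5.25 ± 0.56, adjusted p = 0.0019) and the exchange factor Mcf2l (-5.08 ± 0.44, adjusted p = 0.00078). The other probe set of Mcf2l changed by -0.40 (adjusted p = 0.92).

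**Figure D3:**
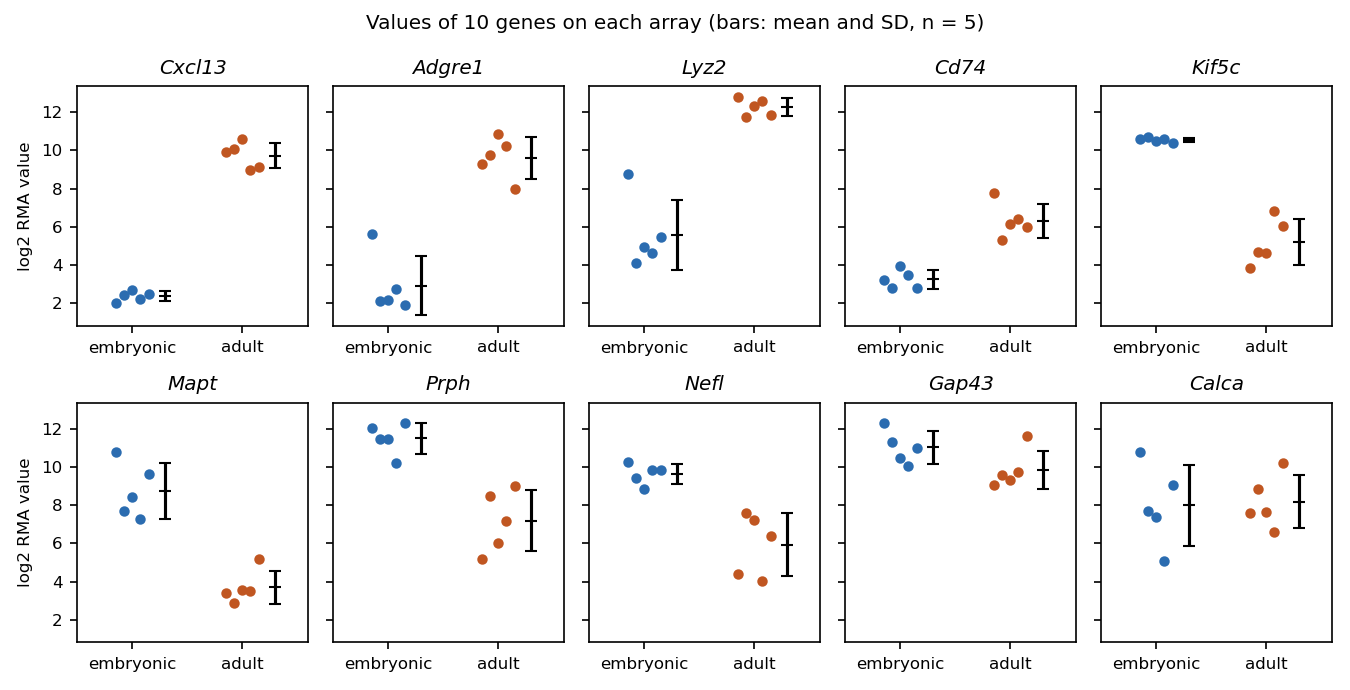
Log2 RMA values of 10 genes on each of 5 embryonic (blue) and 5 adult (orange) arrays, with mean and SD beside the points. Cxcl13, Adgre1, Lyz2 and Cd74 were higher and Kif5c, Mapt, Prph and Nefl lower on all adult arrays, while values of Gap43 and Calca overlapped between stages.

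Of 35 transcripts earlier reported in axons, 6 fell and 0 rose, with 8 lower and 3 higher when adjusted over the list alone. All 6 also stand on the neurofilament, tubulin and microtubule list and were counted there, so they are not a separate result. The 3 with the largest falls were Mapt, Prph and Nefl (list adjusted p = 7.5e-05; adjusted p = 0.35 with an estimated correlation). Oxidative phosphorylation had a median change of -1.10 over 76 genes, of which 1 fell, and 18 when adjusted over the list alone. That gene was Cox6b1 (-1.99 ± 0.38, adjusted p = 0.043), whose values overlapped between stages. The list was called lower (adjusted p = 5.1e-17; adjusted p = 0.27 with an estimated correlation), with medians of -0.21 within arrays of wide spread and -1.80 within those of narrow spread. Cytosolic ribosomal proteins had 0 of 45 genes past the threshold by limma and 2 lower when adjusted over the list alone (list adjusted p = 0.00064; adjusted p = 0.70 with an estimated correlation), with medians of 0.28 and -0.90 within arrays of wide and narrow spread. Quantile scaling and cyclic loess ended this list's call (adjusted p = 0.27 and 0.92), the latter with a median of 0.05.

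Among 45 nociception receptors, channels and peptides 0 passed the threshold over all genes or over the list alone (camera adjusted p = 0.21, and lower at 0.030 without adult replicate 2). Calca, the precursor of calcitonin gene-related peptide, was at 7.99 ± 2.11 in embryonic and 8.17 ± 1.39 in adult samples (SD, n = 5; adjusted p = 0.99). The sodium channel Scn10a was at 6.77 ± 1.27 and 5.40 ± 0.91 (adjusted p = 0.52), and the heat receptor Trpv1 at 3.74 ± 1.69 and 2.51 ± 0.52 (adjusted p = 0.66). Trpv1 was above background on 2 embryonic and 0 adult arrays. Many of the 45 genes lay near the background level in both stages, where a change could hardly be seen. Voltage-gated channels had 0 of 42 genes past the threshold by limma and 2 lower when adjusted over the list alone. That list was called lower (adjusted p = 0.0079; adjusted p = 0.59 with an estimated correlation), with an adjusted p of 0.20 after leaving out 1 array. Elavl4, a neuronal RNA-binding protein, fell (-3.79 ± 0.57, adjusted p = 0.012) in a list of 43 RNA binding and transport genes that was not called (adjusted p = 0.078), though it was called lower without embryonic replicate 3 (0.0061), adult replicate 4 (0.0099) or adult replicate 5 (0.030), with 3 lower when adjusted over the list alone.

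Markers of other cell types were tested in the same way. Of 11 blood cell markers 1 fell, and 5 when adjusted over the list alone, and the embryonic globin Hbe1 changed by -3.12 ± 0.46 (adjusted p = 0.011; list adjusted p = 6.7e-05; adjusted p = 0.22 with an estimated correlation). Schwann cell, satellite glial, fibroblast and endothelial lists had 0 called genes by limma and camera adjusted p values of 0.22, 0.95, 0.48 and 0.98, and the Schwann cell list was called higher without adult replicate 4 (0.033). Adjusted over the list alone, 1 Schwann cell and 1 satellite glial gene were higher and 0 of the fibroblast and endothelial lists passed. Nuclear transcription factors of sensory neurons, a marker of cell bodies, had 0 of 22 genes past the threshold over all genes or over the list alone and were called lower as a list (adjusted p = 0.0028; adjusted p = 0.27 with an estimated correlation), and muscle markers likewise had 0 of 27 genes called and 2 lower when adjusted over the list alone (adjusted p = 0.021; adjusted p = 0.62 with an estimated correlation). Cell cycle genes were called higher as a list (adjusted p = 9.0e-06; adjusted p = 0.59 with an estimated correlation), with 2 higher and 1 lower when adjusted over the list alone. The only called member of 58, Ccnd2, fell (-3.26 ± 0.57, adjusted p = 0.025). The cell cycle median was 2.32 within arrays of wide spread and -0.25 within those of narrow spread.

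By camera 17 of 30 lists were called, 6 higher and 11 lower, and 0 with an estimated correlation, where 8 had an unadjusted p under 0.05, while the directional fry test called 9. By an exact permutation test of each list's mean per array, chosen after seeing the data, 12 lists were under 0.05 and 7 after adjustment. These 7 were macrophage and leucocyte markers, cytokines, antigen presentation, the interferon response, motors, axon growth and blood cell markers, each at the smallest p that 252 labellings allow, 0.0079 (adjusted p = 0.034). The neurofilament, tubulin and microtubule list and the synaptic list each had an exact permutation p of 0.016 and missed the threshold after adjustment (0.053). Of the 17 called lists, cell cycle, ribosomal, oxidative phosphorylation, lysosome and muscle lists had exact permutation p values of 0.38, 0.26, 0.079, 0.079 and 0.071.

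Genes above background on all 5 arrays numbered 3980 in embryonic and 3286 in adult samples, with 2385 in both. Leaving out adult replicate 3 gave an adult count of 4419, but a gene then had to pass on fewer arrays, so the count could only rise. With 4 of 5 arrays required in both stages, the counts were 5821 in embryonic and 5453 in adult samples. The mean per array had the other order, 7142 in embryonic and 7320 in adult samples (exact permutation p = 0.87). On all embryonic and no adult array were 10 genes, 5 of them called lower in adult samples, and on all adult and no embryonic array 25 genes, 15 of them called higher. Arrays of the same stage correlated at a mean Pearson r of 0.79 (embryonic) and 0.73 (adult) over probe sets, which are not independent replicates, and arrays of different stages at 0.70. The first principal component, with 27.5% of the variance, followed the spread of the arrays. Among the arrays of narrow spread it also separated the stages (-5.3 to 15.7 on embryonic and 63.4 to 96.4 on adult arrays). The second, with 22.7%, separated the stages over all arrays.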

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

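The tests of leucocyte RNA, of a lower axonal share, of dilution and of labelling were chosen only after the results were seen. The counts of other splits of the arrays were not.

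Poly-A control transcripts were 8.40 higher on the log2 scale on adult than on embryonic arrays, and the 5S ribosomal RNA control probe set changed by -4.03. Neither was part of the gene comparison. Among 100 groups of 5 values, 8 held an array far from the other 4, where chance gives about 1 in 20. Embryonic replicate 1 stood high in Adgre1 (5.61, the others 1.94 to 2.78), Fcgr2b (5.37, the others 2.01 to 2.67) and Lcp1 (7.005, the others 3.23 to 4.21). Adult replicate 5 stood high in Apc2 (6.30, the others 2.62 to 3.41), Cox6b1 (9.76, the others 8.37 to 8.53), Tubb3 (6.31, the others 3.91 to 4.30) and Gap43 (11.60, the others 9.08 to 9.71), and low in the 5S control (2.72, the others 4.87 to 5.62).

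Of 100 splits of the arrays into 5 and 5, the real one included, 2 gave as many called probe sets and 2 as many called genes. So few argue against a chance division of the arrays for both, but do not exclude it, as another split gave more. The real split gave 258 probe sets and 179 genes, and the highest other gave 328 and 209. That other split placed all 4 arrays of wide spread in 1 group, with embryonic replicate 2 as the fifth, and the other 5 drawn splits that did so gave 0 to 65 probe sets and 0 to 48 genes, fewer than stage. With array spread as a block the stage comparison gave 276 genes. For the 17 called lists the splits do not argue against chance, because 21 of the 100 splits gave as many, up to 21 lists.

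In adult samples 12 of 33 macrophage and leucocyte markers were higher, with Lyz2 at 12.27, Fcer1g at 9.85 and Lcp1 at 9.74. The list's median exceeded the highest of the Schwann cell, satellite glial, fibroblast and endothelial medians by 2.50 (95% bootstrap interval over genes 0.25 to 3.78). This cannot decide on a lower axonal share that raises every other cell type alike. The list was taken up after its median was seen to be the highest, and the interval leaves out the spread between arrays. Many endothelial and Schwann cell markers also lay near the background level. Some Schwann cell, satellite glial and fibroblast markers had means well above it in both stages. Examples are Pmp22 (6.86 in embryonic and 9.44 in adult samples), Gja1 (6.82 and 6.61) and Mgp (5.92 and 9.92). RNA of other cells therefore cannot be taken as absent from either stage. RNA of leucocytes in the adult samples is a candidate source, because 34 leucocyte genes outside the fixed lists had a median change of 1.20, above all 10000 level-matched random lists, although only 2 of them passed the test and 4 of the 33 listed markers also stand on other lists. The random lists treat genes as independent and leave out the spread between arrays. An exact permutation test of the mean of these 34 genes per array gave p = 0.0079, the smallest it allows. A labelling difference cannot be told apart from stage, because the poly-A controls differed by 8.40 between all adult and all embryonic arrays. Stage itself stays open, and whether such cells lay in the axon compartment was not tested.

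Camera called the cytoskeletal, motor, growth and synaptic lists lower in adult samples, though not with an estimated correlation. A dilution that lowers all members of these lists alike predicts no departure from the median member within arrays. Of members of the called neuronal lists with an embryonic mean above 8, 10 of 35 departed. As that choice favours genes that fell, members with a mean over all arrays above 8 were also taken, and 9 of 21 departed. Several that departed upward, such as Rtn4 and Dynlt3, are also made by other cells, which could supply them and shift the median member. The departures thus argue only against an equal fall of the measured values and cannot decide on a dilution of axonal RNA. Among members made mainly by neurons, a list written after their changes had been seen, 6 of 18 departed by the embryonic mean. By the mean over all arrays 4 of 7 did (Kif5a and Prph lower, Gap43 and Sv2b higher). Without a filter 12 of 36 did, 2 lower and 10 higher, several of these near the background level. The departing members thus differed by filter. On a list made after the changes were seen, this cannot decide whether dilution with such a supply is the whole cause. A part of the fall may be dilution. A labelling difference (8.40 in the poly-A controls) cannot be told apart from stage, which also stays open.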

How the results depend on the processing

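Tests by array spread were chosen after seeing the data. Called lists kept direction and side of the threshold in 320 of 357 planned values and named genes in 560 of 664, with 0 reversed. Lists not called passed the threshold in 10 of 273 planned values, 8 of them without 1 array, and RNA binding under array weights (0.026) and chaperones under cyclic loess (0.041). By spread, nociception (camera adjusted p = 0.0019), chaperones (0.0012), fibroblast (0.00064), translation factors (0.013) and proteasome (1.9e-06) lists passed in the wide arrays. Actin, RNA binding (both 0.038), translation factors (0.0011) and proteasome (0.0041) passed in the narrow ones. Translation factors and proteasome were higher in adult samples in the wide arrays (medians 0.57 and 0.88) and lower in the narrow ones (-0.75 and -0.86). A filter on weak probe sets gave 420 probe sets and 299 genes, because fewer were tested (15580 and 9662), and correlations of 0.66 within and 0.55 between stages. An estimated correlation left 0 lists and fry 9. Without 1 array there were 150 to 339 probe sets, 101 to 248 genes and 16 to 19 lists. Of 35 called named genes, 15 lost the call in at least 1 such run, at highest adjusted p values of 0.051 to 0.11. Quantile scaling ended the calls of Kif5a, Nefl, Ccnd2 and Rab3a, and cyclic loess those and Cox6b1, and both ended that of the ribosomal list. The weak probe set filter ended the sensory transcription factor and muscle lists, array weights the muscle list, the other variance model Cox6b1, Rab3a and Chga, the mean of probe sets Rab3a, median scaling Kif5a and Cox6b1, and the suffix filter Mapt and Tubb3. The list calls lost without 1 array were muscle, channel and sensory transcription factor lists.

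Whether the replicate numbers pair the samples is not given in the sources used here. Same-number deviations correlated at -0.08, 0.04, 0.17, -0.10 and 0.25, and only replicate 5 correlated best with its own number. These values give little sign of pairing but do not exclude it. The replicate block gave 135 genes (104 shared), 191 probe sets and 17 lists. It ended the calls of Akr1b8 (limma adjusted p = 0.10), Kif5a (0.071), Dcx (0.053), Nefl (0.11), Ccl2 (0.12) and Cox6b1 (0.095), and cholesterol synthesis turned direction (limma camera adjusted p = 0.94).

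With array spread as a block there were 401 probe sets and 276 genes. The 4 wide arrays gave 0 probe sets and 0 genes by limma (4657 and 2810 at an unadjusted p under 0.05). They gave 7364 embryonic, 8977 adult and 6899 shared genes above background. The 99th percentile gave 2152 adult and 1491 shared genes, and 4 of 5 arrays gave 5453 and 4401. Signal over background limits which genes count as present.

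Turned in direction, with adjusted p, were the following. Scaling: cholesterol synthesis 0.92 (quantile), actin 0.63, proteasome 0.45 and endothelial 0.92 (cyclic loess), endothelial 0.99 (median). Array weights: cholesterol 0.71, satellite glia 0.99, Calca (change -0.19). Suffix filter: cholesterol 0.79, Calca -0.53. Mean of probe sets: proteasome 0.96, Calca -0.18. Fry: satellite glia and endothelial 0.98. Spread block: cholesterol 0.97. Wide arrays: actin 0.11, ribosomal 0.13, translation factors 0.013, proteasome 1.9e-06, RNA binding 0.81, endothelial 0.47, Calca -1.51. Narrow arrays: nociception and cell cycle 0.48, channels 0.78, glycolysis 0.61, cholesterol 0.73, chaperones 0.72, satellite glia 0.43, fibroblast 0.071, Trpv1 change 0.14. Called among the full set of arrays were only the ribosomal, cell cycle and channel lists. The cause was not tested.

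Some lists and Calca also turned without 1 array, over these ranges of adjusted p: actin 0.14 to 0.98, translation factors 0.010 to 1.00, glycolysis 0.17 to 0.87, cholesterol 0.16 to 0.99, proteasome 0.094 to 0.99, chaperones 0.036 to 0.98, satellite glia 0.51 to 0.99, fibroblast 0.091 to 0.97, endothelial 0.43 to 0.99. The change of Calca ranged from -0.55 to 0.87.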

Other observations

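The tests of imprinted genes were chosen only after H19, Igf2 and Nnat had been seen among the falls.

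Lists of housekeeping and stress genes gave no called member by limma beyond those named in the report. Actin regulators (38 genes), translation factors (52), glycolysis (17), cholesterol synthesis (20), chaperones (34) and injury and regeneration genes (37) had camera adjusted p values of 0.59, 0.29, 0.78, 0.95, 0.26 and 0.15, and the proteasome 0.95. Translation factors were called lower without adult replicate 4 (0.010) or 5 (0.027), and chaperones higher without adult replicate 2 (0.036). The median change of cholesterol synthesis genes (-0.11) and of satellite glial markers (-0.09) was negative while camera gave the other direction, and endothelial markers had a median of -0.09 and a mean of 0.03. Adjusted over the list alone, actin regulators had 1 higher and 2 lower, glycolysis and cholesterol synthesis 1 higher each, injury genes 1 lower, and translation factors and chaperones 0.

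Among the 92 genes lower in adult samples were 3 imprinted genes, which are expressed from the copy of a single parent. H19 fell by 4.21 ± 0.47 on the log2 scale (SE, n = 5; adjusted p = 0.0022), Igf2 by 3.67 ± 0.62 (adjusted p = 0.022) and Nnat by 4.44 ± 0.42 (adjusted p = 0.0010). The hypothesis that imprinted genes fall as a group was tested on 24 others, none of which passed the gene test. Their median change was -0.15, 15 of 24 were negative, camera gave p = 0.042 with an estimated correlation, and an exact permutation test of their mean per array gave p = 0.071. The camera result suggests a shared fall and the permutation test does not reach the threshold, so the hypothesis stays open. Meg3 (-4.20) and Plagl1 (-3.15) had the largest negative changes of the 24, and Dcn (4.26) the largest positive change.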
